A study of Homo sapiens with 36 samples.

How the data were processed

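Polyadenylated RNA from 7 human T cell neoplasm lines carrying a short hairpin RNA against GATA3 or a scrambled control hairpin was sequenced in 36 libraries, 18 of each arm. Per the submitters' protocols, cells were grown in RPMI with 10% fetal bovine serum, RNA was isolated with the RNeasy mini plus kit, and libraries were made from 50 ng of total RNA with the NEBNext Poly(A) module and the xGen Broad-range RNA kit. The values are expected counts per gene that, per the submitters' processing notes, the authors made by trimming reads with cutadapt 2.3, aligning them with STAR 2.7.8a to GRCh38 and counting with RSEM 1.3.3. The deposited values were already whole, so rounding changed none of them. The annotation release and strand setting of the counting are not given in the sources used here. Of 60628 deposited gene identifiers 58516 (96.5%) are in GENCODE 29, which gave the coordinates and overlaps.

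Samples were grouped by line and arm from the titles (14 groups), and lines by the class in the labels (3 CTCL, 4 T-ALL). The cell line field of SUP-T1 libraries carries running numbers, and the titles, which all say SUP-T1, were used. Library totals ran from 18.62 M to 50.63 M. Among genes with at least 20 counts, the scatter of replicates per gene was 3.67 to 154.5 in units of Poisson variance, and the lowest Pearson correlation between replicates was 0.978. Replicate numbers were checked as a pairing: the 17 correlations between residuals of same-numbered libraries ran from -0.0596 to 0.0937, and none was over 0.1, so samples were not paired.

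Lists of genes, tests, thresholds and alternatives were chosen before the data were examined, except those named here and in the closing section as chosen later. Within lines, edgeR 4.0.16 (R 4.3.3) fitted all 36 libraries with 1 mean per group, using TMM scaling, filterByExpr (21138 genes tested) and quasi-likelihood F tests. Each line was tested by its own contrast, and p-values were adjusted by the Benjamini-Hochberg method over tested genes with a threshold of 0.05. The common dispersion was 0.01178. For tests over lines, counts were summed per line and arm (20773 genes tested), with line as covariate for the mean response and an interaction of arm and class for the class difference. Summed controls of 3 CTCL and 4 T-ALL lines were compared at baseline. Levels are CPM on the TMM-scaled library total.

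Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, over lists with at least 5 tested members, with GATA3 taken out. The fry test of the same lists, which asks whether a set moves one way and not whether it differs from other genes, was run and is not reported here. Sharing between the 21 pairs of lines was tested with one-sided Fisher's exact tests against independent lists, adjusted over the 21 pairs. Alternatives were DESeq2 1.42.0, DESeq2 size factors, limma-voom, no filter, a filter of 10 counts in 2 libraries, a separate fit of each line, replicate number as a block, lines as fixed, a minimum absolute log2 fold change of 1, and leaving out each library or line. Added after values were seen were fits without SUP-T1 and THP6 knockdown 2 together, lists of THP6 without that library, and sharing without pairs that hold SUP-T1.

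Genes were named by a fixed rule. GATA3 was named throughout. Each line named the 5 highest and 5 lowest log2 fold changes past the threshold with every knockdown library on one side of every control and a mean of at least 5 CPM. Across lines the rule named the 10 genes with the lowest p where no gene passed, and the 10 genes called the same way in the most lines. Baseline named 8 genes per direction with at least 5 CPM in the higher class. Genes without an HGNC symbol and sex-chromosome marker genes were passed over, and the results of some genes are not reported here. List members were named as examples with preference for low adjusted p, and the 5 genes called without SUP-T1 were chosen after values were seen. Words of 7 bases in 3' UTRs were counted in 10575 of 11618 genes at 5 CPM or more, with UTRs of at least 50 bases, and each was tested against the mean log2 fold change of the 6 lines other than SUP-T1 with Bonferroni adjustment, using Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Figures used matplotlib 3.10.9.

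The tests were also run on simulated data with a dispersion of 0.01 and 200 changed genes. Changes of 1.5-fold were recovered for 74% of genes in H9, 82% in MyLa, 55% in Mac1, 86% in SUP-T1, 79% in CCRF-CEM, 60% in MOLT4 and 80% in THP6, and changes of 2-fold for 98% in MOLT4 and 100% in the other lines. False calls were 5.95%, 3.72%, 6.06%, 1.59%, 5.29%, 1.25% and 3.74% of calls in the same order. Tests over lines recovered 100% of 2-fold changes across lines (1.72% false) and 100% of 4-fold class differences (6.54%), and the baseline test 95% of 16-fold differences (11.8%). In these simulations responses varied between lines with an SD of 0.3 in log2 and levels with an SD of 1, and changed genes were expressed in every line. Class differences planted in the same data were not counted as false across lines. The rates hold for these settings and do not give the power of the tests in the real lines. Camera called 0 of 30 random lists. Their genes were drawn independently of each other, so this does not test the preset correlation on lists of correlated genes.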

Results

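GATA3, a zinc finger transcription factor required for T lineage commitment and for T helper type 2 differentiation, was targeted with a hairpin in 7 human T cell neoplasm lines, and polyadenylated RNA was sequenced in 18 libraries labelled knockdown and 18 labelled control. The labels call 3 lines cutaneous T lymphocytes, here the cutaneous T cell lymphoma (CTCL) class. These were H9 (2 control, 3 knockdown libraries), a clonal derivative of the Sézary line HUT 78; MyLa (MylaCD4+ in the labels, 3 and 3), established from mycosis fungoides; and Mac1 (2 and 2), another cutaneous T cell lymphoma line. The 4 lines of the T-cell acute lymphoblastic leukaemia (T-ALL) class were SUP-T1 (3 and 3), CCRF-CEM (3 and 3), MOLT4 (2 and 2) and THP6 (3 control, 2 knockdown). Knockdown libraries came from cells with a short hairpin RNA against GATA3 and control libraries from cells with a scrambled hairpin. Totals ran from 18.62 M expected counts (THP6 control 3) to 50.63 M (Mac1 knockdown 1). The line accounted for 94.6% of the variance of log2 CPM (counts scaled to the library total), knockdown within line for 2.14% and replicates for 3.21%. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. They also do not say whether all knockdown replicates carried the same hairpin.

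GATA3 (ENSG00000107485, chromosome 10, 8045378 to 8075203, plus strand, GRCh38) was lower in every knockdown library than in every control library of its line in 6 of the 7 lines. It fell from 148 ± 4.49 to 62.2 ± 1.35 CPM in H9 (SD, n = 2 and 3). It fell from 248 ± 6.81 to 151 ± 3.17 in MyLa (n = 3 and 3), and from 90.3 ± 12.3 to 40.8 ± 4.39 in Mac1 (n = 2 and 2). In the T-ALL class it fell from 86.3 ± 5.16 to 44.2 ± 2.12 CPM in CCRF-CEM (n = 3 and 3), from 64.7 ± 0.0992 to 23.6 ± 0.823 in MOLT4 (n = 2 and 2) and from 135 ± 9.88 to 64.6 ± 12.6 in THP6 (n = 3 and 2). The log2 fold changes were -1.25 (SE 0.0899), -0.72 (0.0809), -1.15 (0.102), -0.97 (0.0833), -1.45 (0.105) and -1.06 (0.0941) in that order, with edgeR adjusted p from 1.59e-11 in MOLT4 to 1.31e-06 in MyLa. SUP-T1 went the other way: the 3 libraries labelled control held 24.4, 23.6 and 24.2 CPM and the 3 labelled knockdown 81.3, 77.2 and 86.65 CPM, a log2 difference of 1.76 (SE 0.0856, adjusted p = 6.24e-15). SUP-T1 libraries are therefore named by their labels throughout, and every direction given for SUP-T1 is that of the libraries labelled knockdown against those labelled control. GATA3 overlaps GATA3-AS1 on the other strand, and the strand setting of the counting is not given in the sources used here. Reads from bases shared by exons of both genes could not be told apart if the counting ignored strand. Only whole gene intervals were compared, so whether exons overlap was not checked. Fitted on its own libraries alone, THP6 gave a GATA3 log2 fold change of -1.05 (SE 0.174) with an adjusted p of 0.753.

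**Figure D1:**
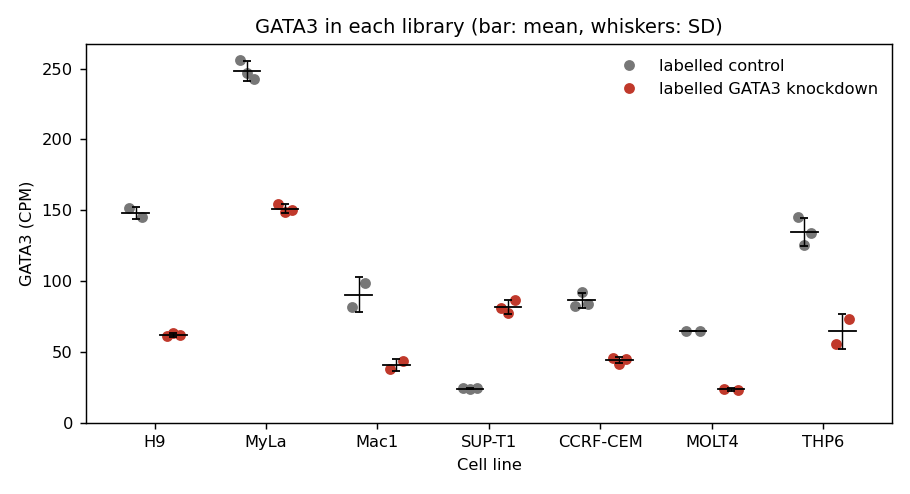
GATA3 level in each of the 36 libraries, in CPM (linear axis from 0), by line and arm, with bars at the mean and whiskers of 1 SD. Knockdown means lie below control means in 6 lines (for example 62.2 against 148 CPM in H9), and the SUP-T1 libraries labelled knockdown lie above those labelled control (81.7 against 24.1 CPM).

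In H9, the costimulatory receptor gene CD28 (ENSG00000178562, chromosome 2, 203706475 to 203738912) rose from 4.19 ± 0.355 to 17.3 ± 1.69 CPM on GATA3 knockdown (SD, n = 2 and 3). The potassium channel gene KCNMA1 (ENSG00000156113, chromosome 10, 76869601 to 77638369) fell from 11.7 ± 0.588 to 1.95 ± 0.442 CPM. LRRN3 (6.24 to 22.7 CPM), the gelatinase gene MMP9 (13.3 to 41.2), LGALS9C (3.44 to 9.66) and GPA33 (2.50 to 6.81) were also higher. ITGB8 (9.69 to 2.60 CPM), BACE2 (9.23 to 2.76) and APOL4 (55.7 to 19) were lower. The edgeR test called 384 of 21138 genes at an adjusted p of 0.05, 180 higher and 204 lower. The count was 108 without control 1 and 162 without control 2. The call of LGALS9C, one of several near-identical galectin genes whose reads can be split, was lost without control 1 (adjusted p = 0.109) or control 2 (0.0574).

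Genes of antigen presentation, cytokine signalling and the Th2 programme were lower in H9 knockdown libraries. Of 22 tested genes of the major histocompatibility complex list, 3 fell over all genes, or 7 with 1 higher when adjusted over the list alone (camera adjusted p = 4.85e-11). These 3 were class II genes, HLA-DPA1 (181 ± 4.67 to 121 ± 2.68 CPM), HLA-DPB1 (83.7 to 58.6) and HLA-DRB1 (86.7 to 63.0), whose reads can be shared within the HLA family. Of 17 Th2 genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.00193). These were the skin-homing chemokine receptor gene CCR4 (74.3 ± 1.16 to 39.8 ± 2.08 CPM, log2 fold change -0.90, SE 0.128), CCR8 (23.9 to 13.1) and the interleukin 33 receptor gene IL1RL1 (2.21 to 0.210). Among 32 cytokine receptor and JAK-STAT genes 4 fell and 1, PIM2, rose (10 and 1 adjusted over the list alone, camera adjusted p = 2.4e-06), with IL10RA at 23.2 and 14.3 CPM and the cytokine gene OSM at 20.1 and 11.4 CPM. Of 26 NF-kB targets 3 fell, 5 over the list alone (camera adjusted p = 2.83e-05), among them ICAM1 (93.2 to 69.1 CPM). Of 38 interferon response genes 3 fell, and 3 over the list alone (camera adjusted p = 0.00125), among them EPSTI1 (30.8 to 19.9 CPM). These 5 lists kept their calls with an estimated correlation (adjusted p from 0.000236 to 0.0211). The 20 genes of the unfolded protein response held 5 that fell, 8 over the list alone, with HYOU1 at 352 and 255 CPM (camera adjusted p = 7.25e-08, adjusted p = 0.0504 with an estimated correlation). Oxidative phosphorylation genes were called higher with 1 of 36 past the threshold, COX7C, also 1 adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.888 with an estimated correlation).

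In MyLa, GBP1 (ENSG00000117228, chromosome 1, 89052319 to 89065360), an interferon-inducible guanylate binding protein gene, rose from 0.556 ± 0.149 to 11.7 ± 1.09 CPM (SD, n = 3 and 3; log2 fold change 4.37, SE 0.229). The long noncoding RNA MIR4435-2HG (2.33 to 9.12 CPM), the integrin gene ITGAX (5.25 to 15.5), RASGRP2 (7.37 to 17.6) and TULP3 (12.3 to 29.4) were also higher. RAI14 (ENSG00000039560, chromosome 5, 34656237 to 34832627) fell from 54.9 ± 2.98 to 18.1 ± 1.99 CPM, and CALD1 (31.8 to 12.1 CPM), FLVCR2 (11.5 to 4.60), PLEKHH2 (33.6 to 14.1) and the synaptotagmin gene SYT4 (195 to 82.3) were lower. In edgeR 397 genes were called, 215 higher and 182 lower. The count was 196, 229 and 249 without control 1, 2 or 3 and 232, 223 and 206 without knockdown 1, 2 or 3.

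In MyLa the list with the lowest camera p was called higher. Of 22 genes of the major histocompatibility complex list 4 rose, 9 adjusted over the list alone, among them HLA-C (684 ± 18 to 895 ± 19.1 CPM), HLA-B (715 to 962) and their transactivator gene NLRC5 (15.2 to 23.7). Its camera adjusted p was 3.28e-11, and 0.000219 as an adjusted p with an estimated correlation, the list of MyLa that held there. T cell receptor genes rose in 3 of 37 cases, 5 over the list alone (TRBC1 3.92 to 6.31 CPM, RASGRP1 4.62 to 7.31, CD3E 0.162 to 0.529), with a camera adjusted p of 0.000791 and an adjusted p = 0.107 with an estimated correlation. Th1 and cytotoxic genes rose in 4 of 29 cases, 5 with 1 lower over the list alone (IL12RB1 14.9 to 27.0 CPM, EOMES 1.01 to 2.54), with a camera adjusted p of 0.0024 and an adjusted p = 0.075 with an estimated correlation. Regulatory T cell markers rose in 2 of 12 cases, 4 over the list alone (TNFRSF1B 53.1 to 74.4 CPM), with a camera adjusted p of 0.00757 and the same adjusted p = 0.075 with an estimated correlation. Lists called lower held few or no called genes. S phase had 0 of 38 by edgeR, and 0 over the list alone (camera adjusted p = 4.6e-06, 0.276 as an adjusted p with an estimated correlation). The mitotic list had 1 of 38, KIF20A at 116 and 67.9 CPM, also 1 over the list alone (0.000229 and 0.381). Ribosomal protein genes had 0 of 40 called (0.00757 and 0.876). In the lists of MYC targets (0.0184 and 0.64) and oxidative phosphorylation (0.022 and 0.876) the 1 called gene of each went up against its list, the amino acid transporter gene SLC7A5 (148 to 182 CPM) and COX7C (118 to 164). All 4 counts are the same adjusted over the list alone.

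In Mac1, the effector protease gene GZMB (ENSG00000100453, chromosome 14, 24630954 to 24634267) rose from 117 ± 16.2 to 630 ± 68.8 CPM (SD, n = 2 and 2; log2 fold change 2.43, SE 0.14). The cytokine gene IL17F (ENSG00000112116, chromosome 6, 52236681 to 52244537) fell from 2973 ± 256 to 777 ± 14.2 CPM (log2 fold change -1.94, SE 0.122). The hypoxia-inducible carbonic anhydrase gene CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159) rose from 6.67 ± 4.25 to 87.9 ± 22 CPM, and its log2 fold change of 3.72 became 4.61 without control 2. The glycolytic aldolase gene ALDOC (71.1 to 350 CPM), TEX19 (7.07 to 32.5) and CD22 (7.09 to 32.6) were higher, and ATP12A (30.3 to 6.05), RNF213-AS1 (9.21 to 2.02), ONECUT2 (13.3 to 3.31) and BMP2 (24.6 to 7.64) were lower. GZMB, CA9 and RNF213-AS1 overlap genes on the other strand, and the last lost its call without knockdown 2 (adjusted p = 0.0564) or control 1 (log2 fold change -1.50, adjusted p = 0.156). Calls numbered 1668 in edgeR, 1171 higher (70.2%) and 497 lower. The count was 562 and 1033 without control 1 or 2 and 803 and 996 without knockdown 1 or 2, and a separate fit of the line gave 49.5% higher.

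Antigen presentation, interferon, cytokine signalling and cytotoxic genes were higher in Mac1 knockdown libraries. Of 22 genes of the major histocompatibility complex list 11 rose, 16 with 1 lower adjusted over the list alone (camera adjusted p = 1.56e-11), including HLA-F (97.8 ± 1.09 to 151 ± 6.48 CPM) and B2M (1817 to 2624). Interferon response genes rose in 10 of 38 cases, 14 with 2 lower over the list alone (camera adjusted p = 4.92e-06), with IFI6 at 8.87 and 17.2 CPM. Of 32 JAK-STAT genes 12 rose and 1 fell, 13 and 1 over the list alone (camera adjusted p = 5.59e-08), including IL2RG (84.4 to 145 CPM) and SOCS3 (804 to 1458). NF-kB targets rose in 6 of 26 cases, 9 over the list alone (camera adjusted p = 0.000954), with the chemokine gene CXCL10 at 44.2 and 115 CPM. Th1 and cytotoxic genes rose in 7 of 29 cases, 8 with 1 lower over the list alone (camera adjusted p = 0.00111), among them the perforin gene PRF1 (510 ± 20.4 to 839 ± 65.4 CPM). Immune checkpoint genes rose in 5 of 20 cases, and in 5 over the list alone (camera adjusted p = 0.00201), with TNFRSF9 at 8.41 and 28.3 CPM. These 6 lists held with an estimated correlation (adjusted p from 0.000169 to 0.0321).

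The other 10 lists called in Mac1 did not hold there. MYC targets fell in 8 of 38 cases, 12 adjusted over the list alone (UTP20 71.9 to 40.8 CPM; camera adjusted p = 3.63e-08, adjusted p = 0.0977 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 32 cases, 8 over the list alone (ENO2 53.2 to 145 CPM; 0.000983 and 0.583 in the same order). Cholesterol synthesis genes rose in 5 of 23 cases, 7 over the list alone (HMGCS1 169 to 254 CPM; 0.000983 and 0.401). The p53 targets rose in 5 of 25, 6 over the list alone (GADD45A 59.6 to 142 CPM; 0.00251 and 0.116). Immediate early genes rose in 5 of 20, 6 over the list alone (BTG2 7.42 to 14.2 CPM; 0.00292 and 0.272). Migration genes rose in 3 of 24, 3 over the list alone (ITGB7 112 to 181 CPM; 0.0142 and 0.0752). Integrated stress response genes fell in 3 of 30 cases, 3 over the list alone (CHAC1 17.7 to 5.88 CPM; 0.00431 and 0.583). The T cell receptor list held 7 higher and 2 lower of 37, 8 and 2 over the list alone (LAT 5.66 to 11.1 CPM, the adaptor gene SKAP1 1.99 to 0.723; 0.0228 and 0.272). Ribosomal protein genes held 1 of 40, RPS6 at 1652 and 2302 CPM, and 1 over the list alone (0.00111 and 0.664). Mitochondrial genome transcripts held 0 of 13 past the threshold by edgeR and 3 lower over the list alone (0.000428 and 0.447), and took 1.06% and 1.23% of counts in the control libraries against 0.796% and 0.626% in the knockdown libraries.

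Among SUP-T1 libraries, those labelled knockdown had higher S100A11 (7.61 ± 0.669 to 52.8 ± 4.92 CPM; SD, n = 3 and 3) and lower LTB (ENSG00000227507, chromosome 6, 31580525 to 31582522; 15.6 ± 0.625 to 2.48 ± 0.514), the lymphotoxin beta gene, than those labelled control. LRP4 (ENSG00000134569, chromosome 11, 46856868 to 46918642) stood at 1.09 and 9.60 CPM, the signalling adaptor gene SH2D1A at 37.3 and 172, AEBP1 at 66.3 and 266 and RHOU at 12.7 and 49.7, all higher in the libraries labelled knockdown. The T cell receptor alpha constant gene TRAC (65.4 ± 2.61 against 14.1 ± 1.31 CPM), BMP10 (17.4 against 3.57), TULP3 (28.1 against 6) and DSCAML1 (10.8 against 2.35) were lower in them. With edgeR, the contrast called 3532 genes, 1720 higher and 1812 lower in the libraries labelled knockdown.

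MYC targets in ribosome biogenesis and nucleotide synthesis were higher in the SUP-T1 libraries labelled knockdown in 24 of 38 cases and lower in 1, or 29 and 1 adjusted over the list alone, including NOLC1 (293 ± 8.09 to 416 ± 4.46 CPM) and SRM (128 to 201). The camera adjusted p was 2.71e-11, and the adjusted p = 0.201 with an estimated correlation. T cell receptor genes were lower in 13 of 37 cases and higher in 4, 17 and 6 over the list alone (CD6 172 to 84.4 CPM, and CD247 the other way from 77.1 to 167; camera adjusted p = 0.000685, adjusted p = 0.201 with an estimated correlation). Immediate early genes were lower in 9 of 20 cases, 10 over the list alone (EGR1 35.1 to 11.9 CPM; 0.000214 and 0.31 in the same order). Mitotic genes were lower in 13 of 38 with 1 higher, 16 and 1 over the list alone (TTK 177 to 107 CPM; 0.000436 and 0.804). Cholesterol synthesis genes were lower in 9 of 23, 10 over the list alone (INSIG1 855 to 495 CPM; 0.000911 and 0.804). BCL2 family genes were lower in 4 of 15 with 1 higher, 5 and 1 over the list alone (BMF 69.3 to 17.3 CPM; 0.0293 and 0.314). Oxidative phosphorylation genes were higher in 6 of 36 cases and lower in 1, and 6 and 1 over the list alone (UQCRC2 144 to 244 CPM, COX7C the other way from 228 to 72.7; 0.00689 and 0.995).

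In CCRF-CEM knockdown libraries, CD1B, which encodes a thymocyte surface antigen, rose from 5.18 ± 1.61 to 26.6 ± 0.541 CPM (SD, n = 3 and 3), the granin gene SCG2 (ENSG00000171951, chromosome 2, 223596940 to 223602503) from 3.48 ± 1.63 to 44.4 ± 4.60 CPM. FLRT3 rose from 2.41 to 14.4, the immunoglobulin mu gene IGHM from 5.47 to 31.3 and FAM30A from 6.24 to 30. RHEX (ENSG00000263961, chromosome 1, 206052723 to 206102459), a regulator of erythropoietin signalling, fell from 102 ± 5.81 to 19.8 ± 4.48 CPM, CCR4 (ENSG00000183813, chromosome 3, 32951574 to 32956349) from 70.8 ± 4.56 to 15.8 ± 2.91. The hypoxia-inducible factor 2 alpha gene EPAS1 fell from 87.7 to 21.5, WDFY4 from 11.7 to 2.59 and SFN from 10.1 to 2.53. Of all tested genes edgeR called 1783, 635 higher and 1148 lower. The count was 1150 without control 2, 1083 without knockdown 2 and 1158 without knockdown 3. Control 2 also held 738 CPM of the signal recognition particle RNA RN7SL1, against 93.3 and 63.1 in controls 1 and 3, and 120 CPM of RN7SK against 12.6 and 5.39.

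Integrated stress response and amino acid supply genes fell in 16 of 30 cases in CCRF-CEM, 20 adjusted over the list alone, among them TRIB3 (252 ± 19 to 130 ± 6.42 CPM) and ATF4 (776 to 573), with a camera adjusted p of 1.5e-12 and an adjusted p = 0.223 with an estimated correlation. Mitotic genes rose in 13 of 38 cases, 20 over the list alone (TOP2A 463 to 618 CPM; camera adjusted p = 1.5e-12, adjusted p = 0.146 with an estimated correlation). Migration and homing genes fell in 10 of 24 cases and rose in 2, 12 and 5 over the list alone, with CD44 (187 to 122 CPM) and the selectin ligand gene SELPLG (30.5 to 18.2) lower and the chemokine receptor gene CXCR4 (152 to 220) higher. This call held (camera adjusted p = 0.000259, adjusted p = 0.0228 with an estimated correlation). Early T lineage genes were called higher with 14 of 51 up and 8 down, and 14 and 8 over the list alone. CD1A (21.95 to 67.7 CPM), SATB1 (129 to 235) and the recombinase gene RAG1 (54.9 to 84.7) rose, and LYL1 (132 ± 11.7 to 41.9 ± 3.05) and IKZF1 (324 to 194) fell (0.00179 and 0.284 in the same order). Cholesterol synthesis genes fell in 10 of 23 cases and rose in 1, 11 and 1 over the list alone (FDPS 518 to 350 CPM, STARD4 the other way from 58.4 to 78.9; 5.07e-06 and 0.282). Glycolysis and hypoxia genes fell in 6 of 32, 9 over the list alone (VEGFA 53.2 to 23.7 CPM; 5.63e-06 and 0.421). MYC targets fell in 5 of 38, 7 over the list alone (4.72e-05 and 0.294). Immediate early genes fell in 5 of 20, 6 with 2 higher over the list alone (IER2 126 to 87.5 CPM; 0.0437 and 0.421).

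Fewer members carried the last calls of CCRF-CEM. Th1 and cytotoxic genes fell in 4 of 29 cases and rose in 1, and 4 and 1 adjusted over the list alone (GZMA 19.2 to 8.33 CPM; camera adjusted p = 0.00594, adjusted p = 0.164 with an estimated correlation). Erythroid genes fell in 2 of 8, 2 with 1 higher over the list alone (EPOR 28.1 to 16.9 CPM; 0.034 and 0.188 in the same order). Oxidative phosphorylation genes were called lower with 3 of 36 down and COX7C up, and the same over the list alone (0.034 and 0.663). Ribosomal protein genes were called lower with 0 of 40 past the threshold by edgeR, also over the list alone (0.0254 and 0.676). The unfolded protein response was called higher with PDIA4 up (357 to 421 CPM) and EDEM1 down (156 to 132) of 20, and the same over the list alone (0.0495 and 0.427).

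In MOLT4, the retinoic acid synthesis gene ALDH1A2 (ENSG00000128918, chromosome 15, 57953424 to 58497866) fell from 644 ± 19.8 to 10.8 ± 1.17 CPM (SD, n = 2 and 2; log2 fold change -5.90, SE 0.167), and the myeloid transcription factor gene CEBPE (ENSG00000092067, chromosome 14, 23117304 to 23119616) from 35.5 ± 0.347 to 1.71 ± 0.248. The imprinted noncoding RNA H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470), which overlaps MIR675, rose from 0.192 ± 0.0847 to 31.5 ± 2.58 CPM. CXCR6 (0.521 to 14.5 CPM), the desmosomal plakophilin gene PKP1 (2.99 to 62.1), REG4 (0.445 to 12.5) and CHST3 (0.138 to 13.5) were higher, the last with an adjusted p of 0.278 in DESeq2. The amino acid transporter gene SLC7A8 (16.1 to 0.362 CPM), LINC00891 (28.3 to 1.64) and NKAIN4 (78.2 to 6.47) were lower. In MOLT4 edgeR called 4054 genes, 1878 higher and 2176 lower. The count was 2260 without knockdown 1, 2307 without control 1 and 2634 without control 2.

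Antigen presentation and interferon genes were higher in MOLT4 knockdown libraries, and erythroid genes lower. Of 22 genes of the major histocompatibility complex list 11 rose and 1 fell, 11 and 1 adjusted over the list alone (PSMB9 24.8 ± 0.171 to 73.2 ± 2.07 CPM, HLA-B 57.1 to 142, B2M 484 to 894; camera adjusted p = 2.46e-10, adjusted p = 0.000184 with an estimated correlation). Of 38 interferon response genes 23 rose and 4 fell, 23 and 4 over the list alone (IFIT3 7.63 to 30.5 CPM, OAS2 4.48 to 17.8, EPSTI1 the other way from 62.7 to 21.9; 2.61e-09 and 0.000184 in the same order). Of 8 erythroid genes 4 fell, 5 over the list alone (NFE2 8.67 to 0.396 CPM, TAL1 40.9 to 21.1; 0.000116 and 0.00527). These 3 lists held with an estimated correlation, and the other 12 called in MOLT4 did not. Unfolded protein response genes fell in 13 of 20 cases and rose in 1, 14 and 2 over the list alone, with the chaperone gene CALR at 1879 ± 28 and 844 ± 17.8 CPM (camera adjusted p = 1.98e-05, adjusted p = 0.147 with an estimated correlation). T cell receptor genes rose in 11 of 37 cases and fell in 4, 13 and 6 over the list alone (CD7 17.6 to 359 CPM, CD3D 282 to 505, RASGRP1 the other way from 48.1 to 18.1; 0.0348 and 0.281). The p53 targets rose in 7 of 25 cases and fell in 3, 7 and 3 over the list alone (CDKN1A 7.38 to 39.1 CPM; 0.00136 and 0.121).

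Proliferation and respiration genes were also called in MOLT4. S phase genes rose in 17 of 38 cases and fell in 1, 18 and 1 adjusted over the list alone (SLBP 122 to 173 CPM; camera adjusted p = 4.02e-05, adjusted p = 0.281 with an estimated correlation). Mitotic genes rose in 11 of 38 and fell in 1, 13 and 2 over the list alone (AURKB 86.6 to 136 CPM, KIF20A the other way from 70.0 to 40.5; 0.00222 and 0.443 in the same order). Oxidative phosphorylation genes rose in 14 of 36, 19 over the list alone (COX5B 112 to 171 CPM; 1.94e-06 and 0.443). Migration genes rose in 10 of 24 and fell in 3, 10 and 5 over the list alone (CCR7 29.95 to 73.1 CPM, ITGA4 the other way from 446 to 167; 0.0141 and 0.105). BCL2 family genes rose in 7 of 15 and fell in 3, 7 and 4 over the list alone (BAK1 54.6 to 97.1 CPM; 0.0498 and 0.281). Th1 and cytotoxic genes rose in 8 of 29 and fell in 1, and 8 and 1 over the list alone (CD8A 34.6 to 64.4 CPM; 0.0107 and 0.121); the median of this list was 0 while its mean of 0.38 and its test were above 0. Glycolysis and hypoxia genes fell in 8 of 32, 9 over the list alone (PDK1 37.5 to 17.3 CPM; 0.00642 and 0.693). MYC targets fell in 7 of 38 with 1 higher, 8 and 1 over the list alone (TFRC 597 to 296 CPM; 0.0313 and 0.558). Ribosomal protein genes were called higher with 2 of 40 up, 1 over the list alone (0.0348 and 0.746).

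THP6 knockdown libraries shared lower ALDH1A2 (44.3 ± 3.92 to 8.64 ± 2.65 CPM; SD, n = 3 and 2) and lower CEBPE (22.7 ± 1.47 to 7.15 ± 0.939) with MOLT4, and lower RHEX (79.6 ± 1.66 to 15.6 ± 14.1) with CCRF-CEM. The T cell signalling gene THEMIS rose from 15.5 ± 0.719 to 82.6 ± 74.3 CPM and the activating receptor gene CD226 fell from 19.2 ± 0.919 to 6.11 ± 6.13. The glucose transporter gene SLC2A3 (ENSG00000059804, chromosome 12, 7919230 to 7936275), similar to SLC2A14, stood at 28.7 ± 3.20 CPM in controls but at 33.0 and 527 CPM in knockdown 1 and 2. CA9 stood at 1.70 ± 0.544 against 3.37 and 17.7, N4BP3 at 1.74 against 10.3 ± 11.4, SDK2 at 9.72 against 42.0 ± 40.8 and LGALS12 at 10.2 against 3.28 ± 2.08. Without knockdown 2 the log2 fold changes were -2.07 for ALDH1A2, -1.80 for CEBPE, -1.64 for RHEX, 0.95 for THEMIS and -0.88 for CD226, all past the threshold with 1 knockdown library left and the spread taken from the other groups, while SLC2A3 (0.21, adjusted p = 0.698), CA9 (1.01, 0.514), N4BP3 (0.32, 0.768), SDK2 (0.45, 0.694) and LGALS12 (-1.11, 0.211) were not. Without knockdown 1 those of RHEX, CD226, THEMIS, SLC2A3, CA9, N4BP3, SDK2 and LGALS12 were -3.82, -3.43, 3.12, 4.2, 3.40, 3.39, 2.87 and -2.50. The edgeR test called 1564 genes, 1175 higher (75.1%) and 389 lower, with limma-voom giving 55.9% higher. The count was 74 without knockdown 2 (23 higher and 51 lower), 7900 without knockdown 1 (3764 higher and 4136 lower), 806 without control 2 and 997 without control 3. Fitted on its own libraries, THP6 gave 0 called genes in edgeR, where in fits of all lines DESeq2 called 2050 and limma-voom 1447.

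Glycolysis and hypoxia genes rose in 27 of 32 cases in THP6, 30 adjusted over the list alone, among them LDHA (950 ± 113 to 1975 ± 1180 CPM) and SLC2A1 (47.4 ± 0.583 to 250 ± 292). The list had a median log2 fold change of 1.05, a camera adjusted p of 4.91e-21 and an adjusted p = 0.35 with an estimated correlation. The mean log2 CPM of this list was 6.14, 6.27 and 6.24 in the controls, 6.30 in knockdown 1 and 7.91 in knockdown 2. Without knockdown 2 the median was 0.09 and the camera adjusted p 0.234. The same library held 1220 CPM of the heat shock gene HSPA1B against 119 in knockdown 1, and 5.42% of counts on ribosomal protein genes against 7.24%. Mitotic genes rose in 19 of 38 cases, 23 over the list alone (MKI67 288 ± 42.4 to 801 ± 524 CPM; camera adjusted p = 1.14e-12, adjusted p = 0.191 with an estimated correlation), and without knockdown 2 the camera adjusted p was 1.78e-16, with 0 of 38 past the threshold by edgeR, 17 higher and 1 lower over the list alone and an adjusted p = 0.205 with an estimated correlation. Immediate early genes rose in 8 of 20 cases and fell in 1, 10 and 1 over the list alone (JUN 40.2 to 140 ± 143 CPM; 2.29e-06 and 0.191 in the same order). The integrated stress response list was called lower with 2 of 30 higher and 2 lower, 2 and 10 over the list alone (DDIT4 284 to 969 ± 917 CPM up, SLC1A5 566 to 438 ± 122 down; 2.04e-06 and 0.576). Ribosomal protein genes held 0 of 40 past the threshold by edgeR, also over the list alone (lower, 2.49e-05 and 0.817). Cholesterol synthesis held 1 of 23 lower, also 1 over the list alone, CYP51A1 (0.0023 and 0.632). Without knockdown 2 these 4 lists were not called: immediate early genes had a camera adjusted p of 0.0606, the integrated stress response 0.436 (median 0.04 against -0.37), ribosomal protein genes 0.392 (median 0.04 against -0.15) and cholesterol synthesis 0.415 (median 0.06 against -0.16). Lists called without knockdown 2 and not with it were S phase (higher, camera adjusted p = 1.33e-05, adjusted p = 0.41 with an estimated correlation), DNA repair (higher, 0.000139 and 0.317 in the same order), MYC targets (higher, 0.000149 and 0.317), the unfolded protein response (higher, 0.000649 and 0.388) and erythroid genes (lower, 0.0391 and 0.317). Of these lists S phase held 2 of 38 genes past the threshold, both higher and 2 over the list alone.

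**Figure D2:**
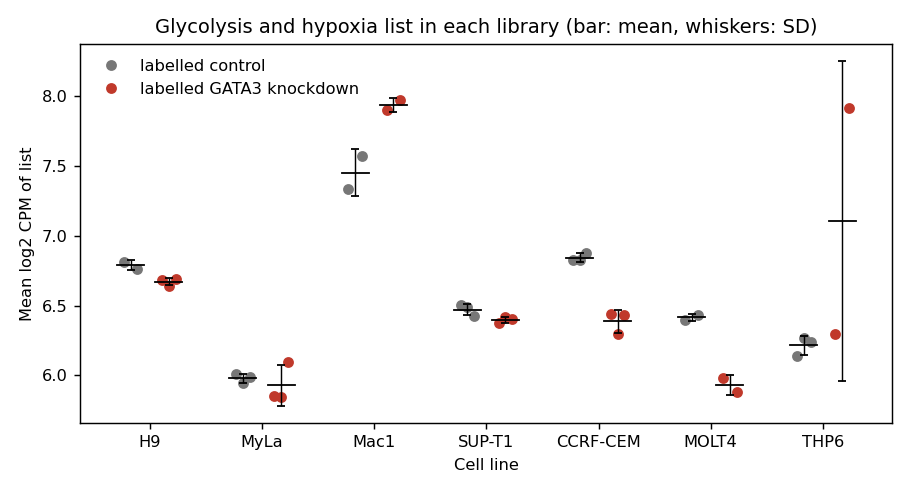
Mean log2 CPM of the glycolysis and hypoxia list in each library (linear axis), by line and arm, with 1 point per library. THP6 knockdown 2 lies at 7.91, and knockdown 1 at 6.30 lies near the THP6 controls at 6.14 to 6.27.

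Over the 7 lines, 73 of the list tests within lines were called with the preset correlation, and 16 of them held with an estimated correlation: 5 in H9, 1 in MyLa, 6 in Mac1, 1 in CCRF-CEM and 3 in MOLT4. The estimated correlation came from all 36 libraries, so the spread between the THP6 knockdown libraries enters it for every line. For glycolysis and hypoxia it was 0.729 in Mac1. In THP6 it was 0.237 without knockdown 2 and 0.258 without knockdown 1. List tests of the other lines were not repeated without these libraries, so lists not holding there may partly reflect THP6. The major histocompatibility complex list held in 4 lines, lower in H9 and higher in MyLa, Mac1 and MOLT4. With DESeq2 size factors 0 of the 73 turned direction, and 2 lost their call, immediate early genes (camera adjusted p = 0.0562) and the unfolded protein response (0.0726) in CCRF-CEM. Marker lists of B cells, NK cells, fibroblasts and epithelium were not called in any line. Counting also the tests across 7 lines and across 6 lines without SUP-T1, 185 list tests were not called, and of these 70 had a median, mean and test that differed in sign.

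A small group of genes moved in nearly every line. TULP3 (ENSG00000078246, chromosome 12, 2877223 to 2941140), a ciliary trafficking gene that overlaps RHNO1 on the same strand, rose in the knockdown libraries of 6 lines by log2 fold changes from 0.99 in H9 to 2.13 in Mac1, and was lower by -2.23 in the SUP-T1 libraries labelled knockdown. The galactosyltransferase gene B4GALT3 (ENSG00000158850, chromosome 1, 161171310 to 161177968), which overlaps PPOX on the other strand, fell in the same 6 lines by -0.82 in THP6 to -1.44 in MOLT4 and stood at 14.2 ± 0.529 and 51.7 ± 0.270 CPM in the SUP-T1 libraries labelled control and knockdown. RABL6 (0.30 to 1.14), MGAT4B (0.37 to 0.94), UBE3C (0.25 to 0.62) and ZNF687 (0.31 to 0.76) rose in those 6 lines, and the palmitoyltransferase gene ZDHHC7 (-0.68 to -0.31) fell. In SUP-T1 these were -1.36, -1.15, -0.81, -0.62 and 0.64, each past the threshold. The respiratory chain gene COX7C rose in 5 lines and was lower in SUP-T1 by -1.65, with 0.17 in THP6 (adjusted p = 0.48). KLHDC7B fell in 5 lines, in Mac1 from 0.290 CPM to a listed 0, and was higher by 1.76 in SUP-T1. MGAT4B overlaps SQSTM1 and ZNF687 overlaps PI4KB. Apart from GATA3, 305 genes were called the same way in at least 3 of the 6 other lines. Of these 186 were called in SUP-T1, and 174 of the 186 (93.6%) went against the other lines. The share going against the other lines was 4% to 16.1% when each of those 6 lines was set against the rest of the 6, with SUP-T1 left out.

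**Figure D3:**
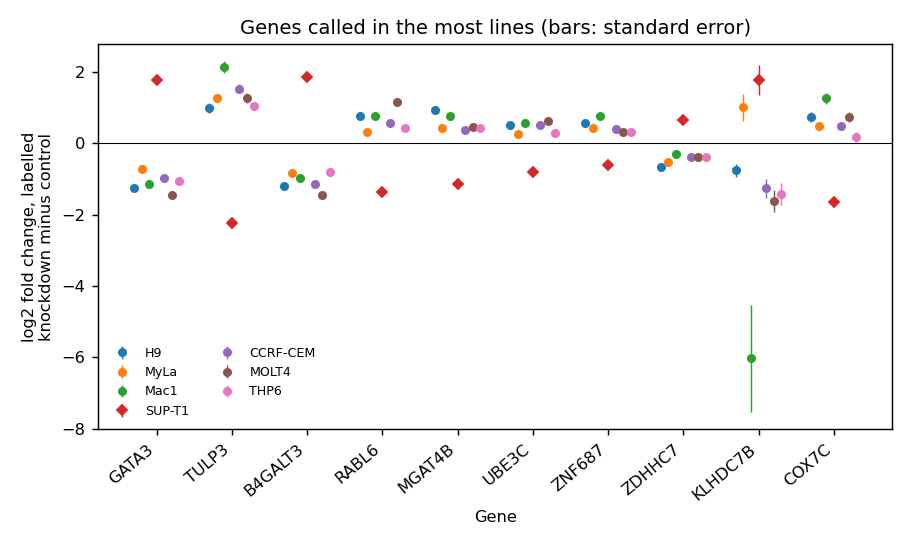
Log2 fold changes with whiskers of 1 SE for the 10 genes called the same way in the most lines, knockdown minus control, 1 marker per line, with SUP-T1 as diamonds for the libraries as labelled. For TULP3 the SUP-T1 value is -2.23 against 0.99 to 2.13 in the other lines, and for GATA3 it is 1.76 against -1.45 to -0.72.

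Responses were shared between lines beyond independent lists. CCRF-CEM and MOLT4 shared 371 lower genes where 118 would be shared by independent lists of these sizes (one-sided Fisher's exact test, adjusted p = 6.08e-98) and 180 higher genes against 56.4. Mac1 and MOLT4 shared 265 higher genes against 104 (adjusted p = 1.29e-47), CCRF-CEM and THP6 123 lower genes against 21.1, and H9 and Mac1 65 higher genes against 9.97. In the same order of pairs, genes called in opposite directions numbered 191 against 167, 192 against 165, 64 against 75.5 and 22 against 15.5. Expected counts treat all 21138 tested genes as equally likely to be called. Lists of better measured genes can therefore exceed them in either direction. In the 15 pairs of lines without SUP-T1, 30 of 30 tests of shared direction passed, and 11 of 30 of opposite direction. With separate fits of each line, in which edgeR called 0 genes in THP6, 17 of the 42 tests of shared direction over all pairs passed, against 31. Without knockdown 2, 74 genes were called in THP6, against 1564. In the 6 pairs with SUP-T1, 1 of 12 tests of shared direction passed and 12 of 12 of opposite direction. SUP-T1 and MOLT4 shared 961 genes called in opposite directions against 338, with SUP-T1 taken by its labels. Each line has its own control libraries. Across genes, which are not independent replicates, correlations of log2 fold changes lay between -0.0714 and 0.0667 (Pearson) and between -0.193 and 0.132 (Spearman) over the 21 pairs.

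Whether GATA3 knockdown changed a gene across lines was tested on counts summed per line and arm, with SUP-T1 as labelled. RHEX (log2 fold change -2.29, SE 0.226, adjusted p = 0.0665) came closest, and GZMB (2.38, 0.213), CDRT4 (-1.74, overlapping TVP23C), the neutrophil protease gene CTSG (-1.14), the VEGF receptor gene FLT1 (-0.84), SPOCK1 (-0.58), SLC43A1 (-0.59), ITGAX (1.22), DERPC (0.41) and GAB2 (-0.38) followed by p, the last 8 with adjusted p of at least 0.973. The edgeR test called 0 of 20773 genes, with 566 at an unadjusted p under 0.05, where DESeq2 called 1 and limma-voom 2. GATA3 itself was at -0.76 (SE 0.316, adjusted p = 1). Without SUP-T1, 5 of 20253 genes passed, chosen after their values were seen: GATA3 (-1.11, SE 0.0903, adjusted p = 0.00319), B4GALT3 (-1.08, 0.00319), RHEX (-2.31, 0.00978), GZMB (2.44, 0.00978) and TULP3 (1.34, 0.0143). Without Mac1, 1 gene was called. RHEX was at a level above 5 CPM in CCRF-CEM and THP6 and GZMB in Mac1, so both rest on few lines.

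For gene lists across lines, camera called 13 of 30 and none held with an estimated correlation, where 0 were called. Integrated stress response genes had the lowest p (lower, median log2 fold change -0.18, camera adjusted p = 2.2e-16, adjusted p = 0.404 with an estimated correlation), with 0 of 31 past the threshold and 2 lower over the list alone. Higher were the interferon response (3.34e-05 and 0.625 in the same order), Th1 and cytotoxic genes (0.000702 and 0.463, with 1 higher over the list alone), the mitotic list (0.00144 and 0.793), the major histocompatibility complex (0.00309 and 0.66), oxidative phosphorylation (0.00543 and 0.825), myeloid markers (0.0425 and 0.463, with 1 lower over the list alone), glycolysis (0.0425 and 0.899) and mitochondrial genome transcripts (0.0431 and 0.825). Lower were cholesterol synthesis (0.00333 and 0.66), MYC targets (0.00977 and 0.825), erythroid genes (0.01 and 0.66) and the unfolded protein response (0.0128 and 0.66). All 13 had 0 members past the threshold over all genes by edgeR. Within lines, the median of the glycolysis list was positive only in Mac1 (0.29) and THP6 (1.05, and 0.09 without knockdown 2). It was negative in H9 (-0.079), MyLa (-0.036), SUP-T1 as labelled (-0.035), CCRF-CEM (-0.25) and MOLT4 (-0.33). The number of called lists was 3 without MOLT4, 7 without Mac1 and 6 without SUP-T1, of which the stress response (3.77e-10), MYC targets (2.39e-09) and the mitotic list (5.12e-07) had the lowest camera adjusted p. With an estimated correlation their adjusted p was 0.588, 0.588 and 0.744, and none of the lists held.

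The response of GATA3 differed by 0.53 between T-ALL and CTCL lines (SE 0.630, adjusted p = 1), with mean log2 fold changes of -0.52 in the 4 T-ALL lines, SUP-T1 as labelled, and -1.05 in the 3 CTCL lines. Without SUP-T1 the difference was -0.13. The test of a response that differed by class called 0 of 20773 genes in edgeR, with 588 at an unadjusted p under 0.05, while DESeq2 called 9 and limma-voom 0. Without MOLT4 or without MyLa, 1 gene was called.

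Control libraries of CTCL and T-ALL lines were compared at baseline. The invariant chain gene CD74 stood at 4744 ± 3410 CPM in CTCL lines (SD, n = 3 lines) and 0.107 ± 0.0772 in T-ALL lines (n = 4 lines; adjusted p = 0.0127). HLA-DPA1 stood at 820 and 0.0895 and HLA-DPB1 at 507 and 0.0133, the last pair overlapping on opposite strands. The aryl hydrocarbon receptor gene AHR (84.5 and 0.00617 CPM), the chemokine gene CXCL10 (46.6 and 0.00335), EBI3 (97.4 and 0.00309), ENPP2 (107 ± 140 and 0.00760) and NUDT16 (31.8 and a listed 0) were also higher in CTCL lines. T-ALL lines had higher CDCA7L (145 ± 29.2 against 0.00617 CPM, adjusted p = 0.0045), ARPP21 (104 against a listed 0), APBB1IP (96.7 against 0.0536), the desmoglein gene DSG2 (78.9 against 0.0333), BEX4 (57.1 against 0.00617), NRIP1 (39.1 against 0.0123), PTPRD (17.4 against 0.00581) and TXNRD3 (11 against a listed 0). GATA3 did not pass (log2 difference -1.10, T-ALL minus CTCL, SE 0.582, adjusted p = 0.463). SUP-T1 entered with its libraries labelled control, in which GATA3 (24.4, 23.6 and 24.2 CPM) was lower than in those labelled knockdown. The edgeR test called 52 of 18565 genes, 14 higher in T-ALL and 38 higher in CTCL lines. DESeq2 called 1957, 949 and 1008 in the same order. The edgeR count was 338 without H9 (155 and 183), 12 without Mac1, 14 without MyLa, 30 without SUP-T1, 20 without CCRF-CEM, 22 without MOLT4 and 15 without THP6. Of the 16 named genes, CD74 and CDCA7L kept an adjusted p under 0.05 whichever line was left out.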

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

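Of the tests in this part, those of a true rise of GATA3 in SUP-T1, both tests of the THP6 library and the share of called genes that went against the other lines were chosen after the result was seen. Chance marks about 1 in 20 groups of this size in the gap test. That rate does not hold here, because the 10 genes were chosen for moving the same way in 5 or 6 lines, which builds a gap to the remaining line into the choice.

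For 9 of the 10 genes called the same way in most lines, 1 line lay far from the rest, measured as the gap to the nearest line over the range of the 7 log2 fold changes. These gaps were 0.771 for GATA3, 0.738 for TULP3, 0.811 for B4GALT3, 0.664 for RABL6, 0.727 for MGAT4B, 0.740 for UBE3C, 0.675 for ZNF687, 0.717 for ZDHHC7 and 0.628 for COX7C. In each case the line was SUP-T1, taken by its labels. SUP-T1 minus the mean of the other 6 lines was 2.86 for GATA3, -3.60 for TULP3, 2.94 for B4GALT3, -2.02 for RABL6, -1.71 for MGAT4B, -1.27 for UBE3C, -1.08 for ZNF687, 1.09 for ZDHHC7, 3.45 for KLHDC7B and -2.29 for COX7C. Over all genes, 7448 had responses that differed among the 7 lines.

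GATA3 was higher in the SUP-T1 libraries labelled knockdown, and an exchange of the control and knockdown labels of the SUP-T1 libraries could give this. The test written beforehand asked that every one of the 4 other genes called over the other 6 lines be reversed in SUP-T1, and it was not met in full: 2 were, TULP3 and B4GALT3, while RHEX and GZMB were below 1 CPM in SUP-T1 and were set aside after this was seen. Of the genes called in SUP-T1 and in at least 3 other lines, 93.55% went against those lines. The share was 4% to 16.1% for each other line, compared without SUP-T1. Genes that follow GATA3 could also be reversed if GATA3 truly rose in SUP-T1. These values therefore cannot tell an exchange of labels from such a rise. If the labels are right and GATA3 rose in SUP-T1 cells that received the knockdown hairpin, sequence words tied to the hairpin should keep their sign. All 4 words had the opposite sign there, but they form 2 overlapping pairs and are not 4 separate observations. Since these words may follow GATA3 itself, the 2 readings cannot be told apart by this test either. No sample was regrouped.

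Genes that moved the same way in most lines could also share seed matches of a hairpin in 3' UTRs. Over the mean of the 6 other lines 4 heptamers passed, TGGATGC (-0.0331) and GGATGCA (-0.0329) in genes lower on knockdown and AAGAGCA (0.0285) and GAAGAGC (0.0286) in genes higher, and all 4 were among the 10 strongest in SUP-T1, with the opposite sign. The words of each sign overlap each other, so they are not separate observations. None of the 4 passed in any single one of the 6 lines, and GGATGCA in Mac1 (0.0074) and AAGAGCA in THP6 (-0.00405) had the opposite sign to the mean. The prediction written beforehand took seed matches to lower their targets. A negative word would then belong to the knockdown hairpin and a positive word to the control hairpin. In their 3' UTRs TULP3, MGAT4B, UBE3C, ZNF687 and COX7C, which were higher, carried a positive word, but so did ZDHHC7, which was lower. KLHDC7B carried a negative word, and B4GALT3, RABL6 and GATA3 carried none of the 4 there. Of all genes searched, 21.8% carried a positive word and 15.2% a negative word. The words were picked for their association with the mean of the same 6 lines in which these genes moved. Carriage of a word by these genes therefore partly restates that choice and is no separate support. Both an effect of hairpin sequence and a response to GATA3 loss stay open for these genes.

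Glycolysis and hypoxia genes were higher in the THP6 knockdown libraries, and the second knockdown library alone may account for this. Without it the median log2 fold change of the list was 0.0882, against 1.05 with both libraries. A lower depth of that library is argued against by its total of 27.28 M, since control 3 had 18.62 M. Whether culture conditions, such as oxygen or cell density, differed for this library was not tested.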

How the results depend on the processing

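The fits without SUP-T1 and THP6 knockdown 2 together were chosen after values were seen. Of the alternatives of counts of called genes and lists, 81 stayed within 1.5 times the first value and 69 did not. Of 1543 alternatives for named genes, 1391 kept direction and side of the threshold, 103 lost the call, 47 gained it and 2 reversed. The cause was not tested for any change below, except that requiring a larger fold gives fewer calls by construction.

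The reversed results were both the class difference of the GATA3 response, 0.53 with all lines, which was -0.13 without SUP-T1 and -0.19 without SUP-T1 and THP6 knockdown 2 (adjusted p = 1). Leaving out 1 line at a time it ran from -0.13 to 0.87, the latter without MOLT4.

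Leaving out 1 library gave 108 to 316 genes in H9 (384 with all), 196 to 249 in MyLa (397), 562 to 1033 in Mac1 (1668), 1083 to 1547 in CCRF-CEM (1783), 2260 to 2775 in MOLT4 (4054) and 74 to 7900 in THP6 (1564). An absolute log2 fold change of at least 1 left 87 genes in H9, 89 in MyLa, 464 in Mac1, 582 in SUP-T1, 402 in CCRF-CEM, 1178 in MOLT4 and 403 in THP6. DESeq2 gave 645 in H9 and 609 in MyLa, and limma-voom 649 in H9. A separate fit of the line gave 1374 in MyLa, 2752 in Mac1 (49.5% higher against 70.2%), 6797 in MOLT4 and 0 in THP6 by edgeR. In fits of all lines, limma-voom gave 1447 in THP6 (55.9% higher against 75.1% by edgeR), and 4613 genes had an unadjusted p under 0.05 there by edgeR.

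With replicate number as a replicate block, calls were 220 in H9, 243 in MyLa and 472 in THP6 (54.9% higher), and stayed within 1.5 times elsewhere: 1386 in Mac1, 3150 in SUP-T1, 1429 in CCRF-CEM and 3630 in MOLT4. Replicate numbers do not pair the samples (correlations from -0.0596 to 0.0937), so the block is reported as an alternative alone.

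Across lines edgeR called 0 genes (566 at an unadjusted p under 0.05), DESeq2 1, limma-voom 2, edgeR without a filter 48, with lines fixed 1073, with replicate block and lines fixed 838, leaving out 1 line 0 to 5, and without SUP-T1 and THP6 knockdown 2 it called 5. For a response differing between classes edgeR called 0 (588 at an unadjusted p under 0.05), DESeq2 9, limma-voom 0, edgeR without a filter 91, with lines fixed 964 and leaving out 1 line 0 to 1. The fits with lines fixed measure spread between libraries, not between lines. At baseline 52 genes were called, 1957 by DESeq2, 100 by limma-voom, 13268 with lines fixed and 12 to 338 leaving out 1 line.

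Of 73 list calls within lines 16 held with an estimated correlation. Across lines 13 lists were called, 0 with an estimated correlation and 3 to 12 leaving out 1 line. THP6 had 6, and 0 with an estimated correlation. Of the tests of shared direction 31 of 42 passed, and 17 with separate fits.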

Other observations

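Of the tests in this part, all counts over other splits of the samples were chosen after the results were seen.

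In MOLT4, genes of the early T lineage and Notch target list that rose with GATA3 knockdown included NOTCH3, from 40.8 ± 1.35 to 287 ± 33.9 CPM (SD, n = 2 and 2), DTX1 from 96.6 ± 0.156 to 743 ± 3.45 and HES4 from 6.68 to 65.6. In the same line MYC fell from 414 to 197 CPM and SOX4 from 728 to 394. The list was not called in MOLT4, with 17 of 51 higher and 16 lower, 18 and 18 adjusted over the list alone (camera adjusted p = 0.641).

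Single genes of the Th2 programme, which GATA3 directs in helper T cells, were called in each CTCL line. Such calls were not particular to this class. In SUP-T1 3 of 17 were higher and 5 lower in the libraries labelled knockdown, with the list not called (camera adjusted p = 0.938). CCR8 fell in H9 and rose in MyLa from 0.385 to 0.932 CPM, where IL9 rose from 19.6 to 40.3. In Mac1, IRF4 rose from 628 ± 13.3 to 1029 ± 86.9 CPM and PPARG from 155 to 216. Among CTCL lines the list was called in H9 and not in the others (camera adjusted p = 0.804 in MyLa and 0.204 in Mac1).

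The heptamers TGGATGC and GGATGCA marked genes lower in knockdown libraries, and it could be that both heptamers lie in the sequence of GATA3 that a hairpin would target. GGATGCA was in 4 of 6 GATA3 transcripts, TGGATGC and the joined TGGATGCA in none. Neither bound set beforehand was met. The absence of TGGATGC from all 6 transcripts argues against both words lying in these GATA3 transcripts. Whether GGATGCA alone lies in the target of a hairpin stays open without the hairpin sequence.

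Other splits of the samples were counted for the number of called genes. In MyLa 397 genes were called by the labels and 0 by edgeR in the highest of the other 9 splits, in SUP-T1 3532 and 1, and in CCRF-CEM 1783 and 0, each with 1 of 10 splits as high. The 10 splits are too few for a share under 0.05. Across the 7 lines the labels called 0 genes in edgeR, so 64 of 64 exchanges of arms called as many by construction, and the count says nothing about chance. The highest other called 7, with SUP-T1 alone exchanged. At baseline between classes, 1 of 35 divisions of the lines called as many as the 52 genes of the labels, and the highest other called 3. The division by the labels thus called more genes than any other. Its share is the lowest possible with 35 divisions, and the count was chosen after the result was seen, so it does not exclude chance. For a response differing between classes the labels called 0 genes, so 35 of 35 divisions called as many by construction, which says nothing about chance, with 0 the highest other in edgeR.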
